A study of Mus musculus with 2 samples.

How the data were processed

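The series profiled H3K27me3, a trimethylated form of histone H3 that the Polycomb repressive complex deposits on silent chromatin, in whole liver of mouse embryos at embryonic day 15.5. Chromatin immunoprecipitation with an antibody to this mark was followed by sequencing. Per the labels, the 2 samples were biological replicates of 1 group, strain B6NCrl, with both sexes pooled. Replicate 1 combined livers of 78 embryos and 3 technical replicates, and replicate 2 combined livers of 62 embryos and 2 technical replicates. The labels number the samples as separate biological replicates, so their spread holds both the differences between pools of embryos and technical differences. The labels name a possible control experiment, which was not analysed here, and with 1 group no comparison between conditions could be made.

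The deposited data were 4 peak lists on the mouse assembly mm10, in the narrowPeak format per the deposited notes. The authors called peaks in each replicate separately and on both replicates pooled, and deposited 1 more list, called the replicated list here, which the deposited notes derive from the pooled list and both replicates' own lists. The peak caller, its version, its thresholds and the control it used are not given in the sources used here. Each peak carries an enrichment value, the signal value column of the authors' caller, and the authors' p-value and q-value on a −log10 scale. These signal values and −log10 values, deposited by the authors, were used only to describe, rank or filter peaks within a list. No list held a peak with a −log10 p below 2. Peak lists hold no read counts, so the sequencing depth behind each replicate is unknown, and no interval that needs a depth is given. A longer list can come from more reads as well as from more signal.

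Peaks were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Coordinates were set beside the GRCm38.p6 sequence and the GENCODE M21 annotation, which share the assembly of the peak lists: 0 peaks ran past a chromosome end, and 0 lay on the Y chromosome or on unplaced sequence. Coordinates are printed counted from 1. Shares of the genome were taken over bases that are not N. A protein-coding gene was called marked when a peak of the replicated list covered at least 1 bp within 1 kb of the gene's annotated 5′ end, over 21938 genes on the assembled chromosomes. These include the genes of the Y chromosome, which could not be called marked and count as unmarked in all shares and backgrounds over all genes. Only the outermost annotated 5′ end was used, so a call does not speak for other promoters of the same gene. The covered share of the 20 kb around a 5′ end was computed for each replicate from its own list and is given as the mean ± SD of both replicates. Promoters were classed as high-CpG when a 500 bp window within 1 kb of the 5′ end had an observed-to-expected CpG ratio of at least 0.75 and a GC content of at least 55%, and as low-CpG when no such window had a ratio of 0.48 or more, with windows every 50 bp. Domains were replicated peaks merged where they lay at most 3 kb apart.

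Overlap between replicates was compared with 1000 circular shifts of one list along each chromosome (one-sided permutation test). Each of 22 gene lists was tested against all other protein-coding genes with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 22 lists. Neighbouring genes share peaks and are not independent, so these p-values describe how the mark is spread over genes in these samples and do not measure variation between animals. On simulated peaks over 21755 genes, 100% of 200 added promoter peaks were called, which checks the code only, since each was placed on a 5′ end. For the list test, genes were marked at random and independently of each other, without peaks. There, 99% of 100 lists of 40 genes with 20 members marked in addition passed, and 3% of 100 lists drawn at random did. The latter rate does not cover neighbouring genes that share peaks. A simulated second list that kept 60.0% of the peaks gave an overlap of 60.9%, and 4.81% after shifts.

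The tests, the 22 gene lists, 33 alternative settings and the rule for named genes were fixed before the data were examined. The rule took 89 genes. From each list it took the 2 marked members with the most covered bases within 10 kb of the 5′ end, and up to 5 marked members where at most 20% of a list was marked. It took up to 5 genes in each of the 10 longest domains, the genes nearest to the 5 replicated peaks of highest enrichment value, and a set of 11 genes named in advance. These are Alb, Afp, Hnf4a, Gata1, Klf1, Hbb-bt, Hoxa13, Hoxd13, Cdkn2a, Actb and Gapdh. Other list members named in the text were picked after their values were seen. List members were matched by symbol or, for renamed genes, by synonym. The erythroid list lost Ahsp, and the imprinted list lost the non-coding RNAs H19, Kcnq1ot1, Meg3, Airn and Hymai. A further imprinted symbol matched a gene already in that list, so its 50 symbols gave 44 genes. Alternatives covered the peak list, the q threshold, the promoter window, the overlap that counts, the background, the null model, the merging distance and leaving out each replicate. A further 5 were added after the data were seen. Tests of gene families by symbol and circular shifts by peak width were also added then. The Fisher's exact test of X-linked against autosomal genes was not among the tests fixed in advance either.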

Results

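H3K27me3, a histone mark of Polycomb-repressed chromatin, was mapped in mouse liver at embryonic day 15.5, when the organ holds hepatoblasts and is also the main site of blood formation. There was 1 group of 2 biological replicates, pools of 78 and 62 embryos. The replicate 1 list had 104738 peaks covering 58.5 Mb, or 2.21% of the genome, and the replicate 2 list had 114063 peaks covering 67.0 Mb, or 2.53%. The pooled list had 142388 peaks over 84.7 Mb. The replicated list, a subset of the pooled one, had 56810 peaks over 62.4 Mb, or 2.36% of the genome. Read depth is unknown from peak lists, so the difference in length between the replicates' lists cannot be set against depth.

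The first question was how far the 2 replicates marked the same places. Broad marked regions were shared and narrow ones often were not. Of the replicate 1 peaks of 2 kb or more, 100% were overlapped by a replicate 2 peak, and so were 99.8% of those from 1 to 2 kb and 92.0% of those from 500 bp to 1 kb, but only 47.2% of those under 500 bp. In replicate 2 the shares overlapped by replicate 1 were 100%, 98.8%, 82.0% and 35.8%. Wider peaks also met a shifted list more often, but far less so: the mean after circular shifts rose from 4.03% under 500 bp to 15.1% from 5 kb in replicate 1 and from 3.56% to 14.6% in replicate 2. Peaks under 500 bp made up 80.0% of the replicate 1 list and 78.5% of the replicate 2 list. In all, 56.8% of replicate 1 peaks were overlapped by at least 1 bp, against a mean of 4.64% and a maximum of 6.28% after circular shifts. The corresponding values for replicate 2 were 47.3%, 4.21% and 5.55%. Both had a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. The Jaccard index of the covered bases was 0.487. Across 21938 genes, which are not independent, the covered share of the 20 kb around the 5′ end had a Spearman correlation of 0.926 between the replicates.

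**Figure D1:**
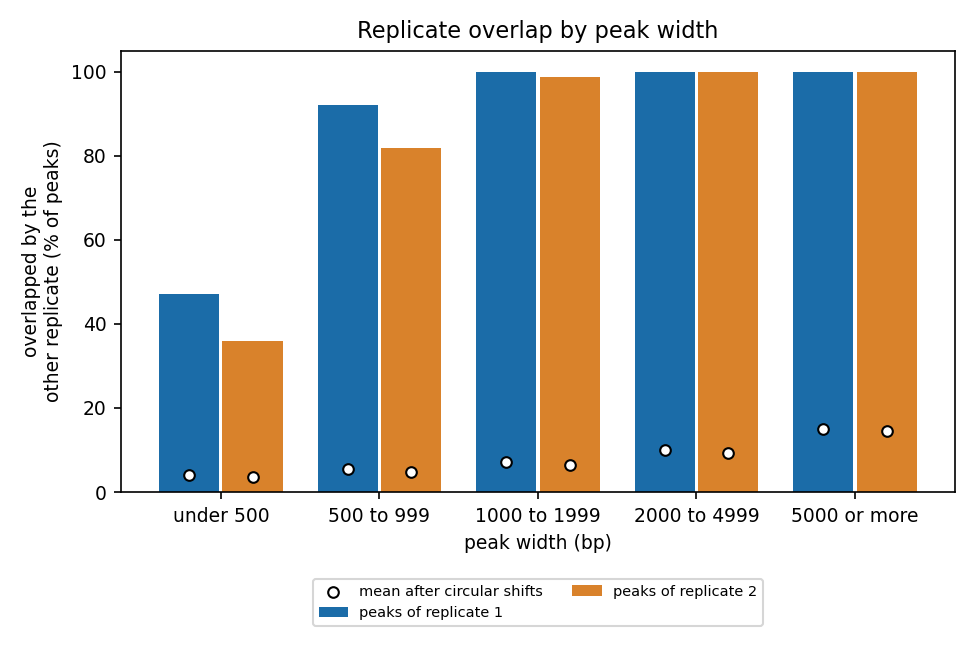
Share of each replicate's peaks (y axis, % of peaks) overlapped by at least 1 bp by the other replicate, by peak width in bp (x axis); bars are the replicates and open points the mean of the same width after 1000 circular shifts. Overlap was 47.2% and 35.8% for peaks under 500 bp and 100% in both replicates from 2000 bp.

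The replicated list held 39.9% of the pooled peaks, and these were the wider and stronger ones, with a median width of 536 bp against 232 bp for the pooled peaks left out. The authors' median −log10 q was 5.67 in the replicated peaks and 2.62 in those left out. Of the replicated peaks, 11284, or 19.9%, were not overlapped by a peak in both replicates' own lists, and these held 7.31% of the replicated bases. Replicate 1 alone lacked 7286 of them, replicate 2 alone 3681, and both lacked 317. With a −log10 q of at least 5 the replicated list shortened to 34214 peaks, and 33380 pooled peaks were covered over at least 50% of their width in both replicates.

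H3K27me3 was concentrated at promoters. The 2 kb around protein-coding 5′ ends took 14.9% of the replicated bases, 9.58 times their share of the genome. Exons outside promoters took 10.5%, which was 2.38 times their share, introns 39.3% and intergenic sequence 35.2%, 0.967 and 0.659 times their shares. The replicates' own lists put 14.6% and 13.9% of their bases at promoters. Of 21938 protein-coding genes, 6378, or 29.1%, were marked. Counted from each replicate's own list, the number was 6973.5 ± 314.66 (SD, n = 2), with 6264 genes marked in both. CpG-rich promoters carried the mark more often: 3866 of 10422 high-CpG promoters (37.1%) and 1651 of 4208 intermediate ones (39.2%) were marked, against 861 of 7308 low-CpG promoters (11.8%). The odds ratio of high-CpG to low-CpG promoters was 4.42. The p of the Fisher's exact test lay below the smallest number the software holds, with a log10 of -331.1 one-sided. The low-CpG class held 1059 olfactory receptor genes, of which 11 were marked, and the odds ratio was not computed without them.

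Developmental regulators, most of them of other tissues and body regions, were marked almost throughout. All 48 neural transcription factors tested were marked, among them Pax6 and Neurod2, regulators of eye and neuron development, whose surrounding 20 kb were covered over 100% ± 0.0 (SD, n = 2). So were all 21 HoxA and HoxB genes and all 18 HoxC and HoxD genes, which set position along the body axis. Hoxa13 was covered over 97.4% ± 1.47 of its 20 kb and Hoxd13 over 99.5% ± 0.13 (SD, n = 2). Of 42 transcription factors of mesoderm, heart and muscle, 38 were marked, with 97.1% ± 1.27 at Tbx2 and 99.1% ± 0.86 at Foxf1, a regulator of visceral mesoderm. The 4 unmarked members were Myog, Myf5, Myf6 and Tbx6. Of 24 transcription factors listed for other endodermal organs, 23 were marked, including the intestinal regulator Cdx2 at 98.5% ± 0.97, and Isx was not. The lists were not cleared of factors that also act in liver, such as Hhex, Tbx3 and Gata4, and these were marked. Secreted developmental signals were marked in 46 of 48 cases, led by Wnt10a at 97.2% ± 0.42 and Wnt3a at 96.1% ± 0.89, and the exceptions were Fgf10 and Fgf20. Genes for ion channels and neuronal receptors were marked in 40 of 46 cases, with 79.6% ± 8.19 at the calcium channel gene Cacna1g. Each of these 7 lists exceeded the other genes, of which 28.9% to 29.0% were marked. The largest adjusted p among them, in two-sided Fisher's exact tests, was 5.95e-10.

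**Figure D2:**
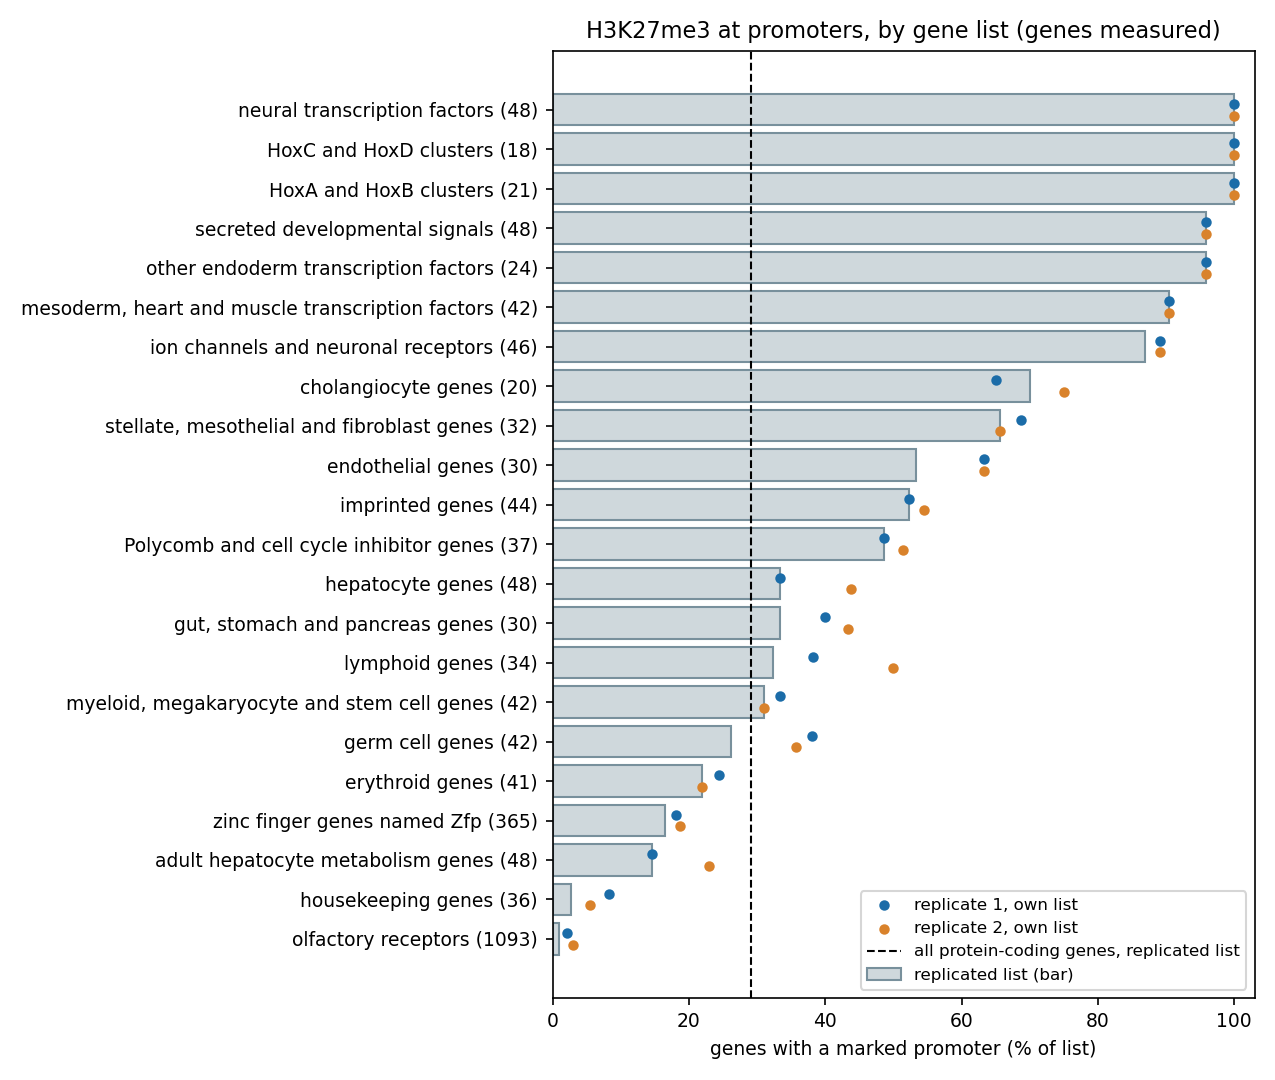
Share of genes with a marked promoter (x axis, % of the list) for 22 gene lists, with the number of genes measured in parentheses; bars show the replicated list, points each replicate's own list, and the dashed line all protein-coding genes (29.1%). Developmental regulators lay at 90.5% or more in both replicates, and olfactory receptors and housekeeping genes at the low end.

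Genes of the liver's own hepatocyte lineage were divided. Alb and Afp, which encode the main plasma proteins of adult and fetal liver, had 0.00% covered in both replicates over the surrounding 20 kb. Hnf4a, a central hepatocyte transcription factor, had an unmarked promoter and 1.87% ± 1.1 of its 20 kb covered (SD, n = 2). Both values refer to its outermost annotated 5′ end and not to other start sites in the gene. The nuclear receptor gene Nr1h4 was also unmarked, with 0.00% covered. Several other hepatocyte transcription factors were marked: Foxa1 was covered over 89.3% ± 2.85 and Onecut1 over 88.5% ± 0.43 (SD, n = 2). Promoters of Foxa2, Foxa3, Prox1, Cebpa, Hnf1a, Nr5a2 and Nr1i3 were also marked. So were some plasma protein genes of the list, Vtn at 53.9% ± 0.89, Apoh at 26.2% ± 2.58, Rbp4 at 16.2% ± 3.23, Trf at 5.08% ± 0.04 and Apoa2 at 3.29% ± 1.53 (SD, n = 2). In total 16 of 48 hepatocyte genes were marked, 33.3% against 29.1% of other genes, and the list did not pass the test (adjusted p = 0.643, Fisher's exact test). Among its members with high-CpG promoters 9 of 10 were marked, and among those with low-CpG promoters 6 of 31. The marked high-CpG members include Dlk1, at 58.0% ± 12.69 (SD, n = 2), which also stood in the imprinted list. Metabolic genes of the adult hepatocyte were marked in 7 of 48 cases (14.6%), 0.501 times the share of other genes (adjusted p = 0.0354, Fisher's exact test). On the replicate 2 list alone, with 22.9% marked, the list did not pass (adjusted exact p = 0.204). It also did not pass with the pooled list, with a −log10 q of at least 5, with at least 25% of the promoter window covered, or when the marked genes were rotated along the gene order (adjusted permutation p = 0.0536). The leading members were Cyp26a1, which encodes a retinoic acid hydroxylase, at 82.5% ± 1.33, and Sds at 28.2% ± 1.99. Hpd, Ass1 and Cyp17a1 were marked too, at 20.1% ± 5.54, 19.7% ± 3.34 and 14.2% ± 6.06. The 2 kb promoter window of Cyp17a1 had 0.0% covered in replicate 1 and 44.7% in replicate 2. Of the adult genes 40 had low-CpG promoters, and against genes of the same CpG class, drawn at random, the list did not pass (adjusted permutation p = 0.931 and a ratio of 0.895).

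**Figure D3:**
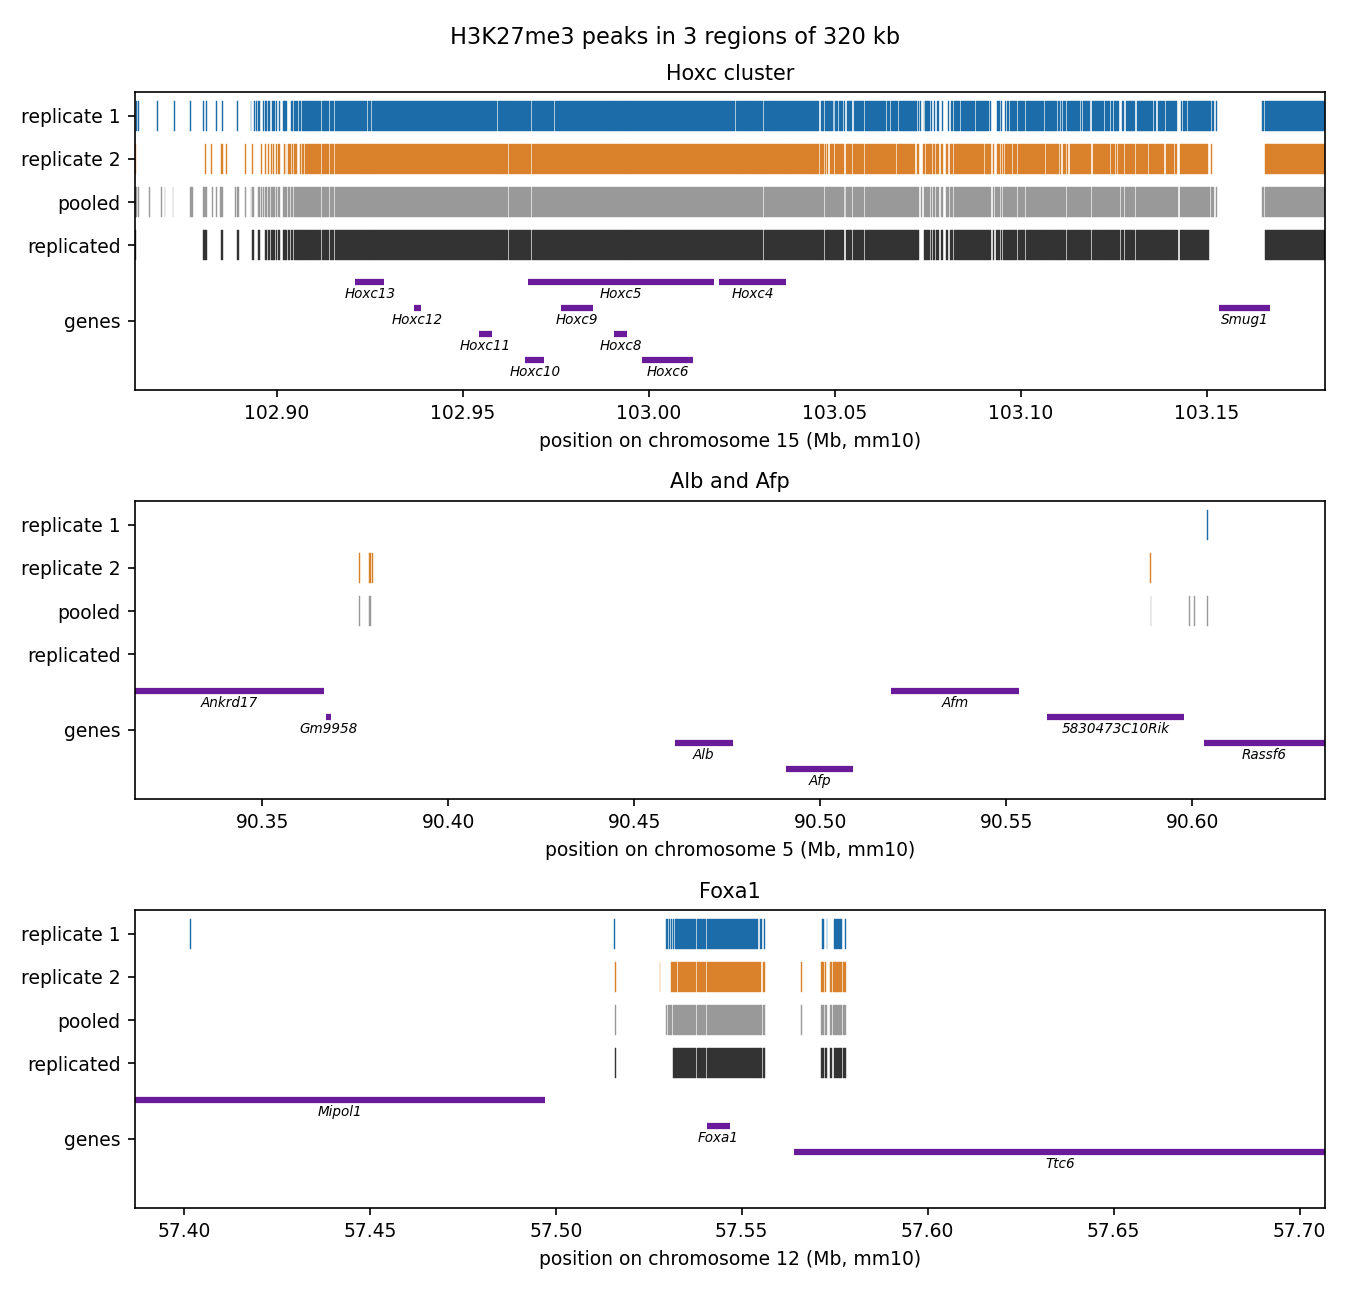
Peaks of the 4 lists (rows, coloured blocks) and protein-coding genes (purple bars) in 3 regions of 320 kb on mm10, with position in Mb on the x axis. Peaks of the replicates covered 76.2% and 77.1% of the Hoxc region, 0.08% and 0.40% of the Alb and Afp region and 8.51% and 9.0% of the Foxa1 region, where they lay mainly around the gene.

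Blood cell genes as groups did not pass the test against other genes, which with lists of this size does not show equal shares. Erythroid genes were marked in 9 of 41 cases (22.0%, adjusted exact p = 0.505). The erythroid transcription factor gene Gata1 and the adult beta-globin gene Hbb-bt had 0.00% covered in both replicates over 20 kb, and Klf1, another erythroid regulator, had 6.23% ± 0.41 with an unmarked promoter (SD, n = 2). The marked erythroid members included Ank1, the gene of the red cell membrane protein ankyrin, at 73.3% ± 2.86, and Tal1, an early blood regulator, at 31.1% ± 3.47. The 2 kb promoter window of Tal1 had 15.6% covered in replicate 1 and 45.4% in replicate 2, against 100% in both at Ank1. For Ank1, a long gene, the value refers to the outermost annotated 5′ end and not to other start sites in the gene. Hba-x, an embryonic alpha-type globin gene, was marked. Of 42 myeloid, megakaryocyte and stem cell genes 13 were marked (31.0%, adjusted exact p = 0.865), with 85.2% ± 0.91 covered at Gata2 and 73.6% ± 2.21 at Gfi1, transcription factor genes of early blood cells. All 10 of that list with high-CpG promoters were marked, and 1 of 29 with low-CpG promoters. Of 34 lymphoid genes 11 were marked (32.4%, adjusted exact p = 0.772), led by Gata3 at 97.9% ± 0.33 and Eomes at 85.9% ± 1.40, regulators of T and natural killer cells. The replicates' own lists marked 38.2% and 50% of the lymphoid genes. The tests of these 3 lists were Fisher's tests, two-sided.

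Markers of the rarer cell types of the liver were marked more often than other genes. Of 32 genes of stellate, mesothelial and fibroblast cells 21 were marked (65.6%, adjusted p = 4.32e-05, Fisher's exact test), led by the transcription factor gene Hand2 at 95.8% ± 0.46 and by Ngfr at 92.0% ± 4.05 (SD, n = 2). Cholangiocyte genes, of the bile duct epithelium, were marked in 14 of 20 cases (70.0%, adjusted exact p = 0.000329), with 94.0% ± 3.07 at Onecut2 and 61.8% ± 3.79 at Muc1. Endothelial genes were marked in 16 of 30 cases (53.3%, adjusted exact p = 0.0116), with 70.9% ± 1.40 at the Notch ligand gene Dll4 and 62.1% ± 2.42 at Sox17. Kdr, Flt1 and Erg were also marked, whereas Pecam1, Cdh5, Tek and Lyve1 were not. Several members of these lists, such as Hand2, Tcf21, Gata4 and Sox17, also stood in the lists of developmental transcription factors. Genes of gut, stomach and pancreas did not pass the test against other genes, with 10 of 30 marked (33.3%, adjusted exact p = 0.772). Ppy, a pancreatic hormone gene, had 66.6% ± 2.18 covered and Muc5ac, a stomach mucin gene, 62.8% ± 12.74.

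Housekeeping genes and large sensory gene families carried little of the mark. Only 1 of 36 housekeeping genes was marked, Eef1a1, with 7.61% ± 2.77 of its 20 kb covered (adjusted p = 0.000259, Fisher's exact test). The replicates' own lists marked 8.33% and 5.56% of the housekeeping genes, against 2.78% here. Gapdh had 0.00% covered in both replicates and Actb 0.46% ± 0.65 (SD, n = 2). Of 1093 olfactory receptor genes 11 were marked (1.01%, adjusted exact p = 2.44e-145), among them Olfr64 and Olfr65 at 25.5% ± 2.42 and 26.3% ± 4.72, and Olfr222, Olfr94 and Olfr71 at 19.3% ± 3.03, 21% ± 2.81 and 12.3% ± 2.56. The replicates' own lists marked 2.10% and 3.02% of the olfactory receptor genes. In replicate 1 the 2 kb promoter windows of Olfr71 and Olfr222 had 0.0% and 2.4% covered, against 23.0% and 44.8% in replicate 2. Of 365 zinc finger genes named Zfp 60 were marked (16.4%, adjusted exact p = 4.73e-08), led by Zfp503 at 85.4% ± 4.41 and Zfp593 at 64.3% ± 2.52. Zfp580, Zfp423 and Zfp536 lay at 56.8% ± 0.53, 56.4% ± 4.21 and 52.1% ± 1.09. The replicated peak in the promoter window of Zfp593 began at position 134245661 of chromosome 4, upstream of the 5′ end at 134245592. It extended away from the gene. Against circularly shifted peaks, which also fall in gene deserts, the housekeeping list lost its call (adjusted permutation p = 0.877) and the Zfp list was marked 2.97 times as often as after shifts.

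Imprinted genes and the list of Polycomb and cell cycle inhibitor genes were marked more often than other genes, the latter not under every setting. Germ cell genes did not pass the test. Of 44 imprinted genes 23 were marked (52.3%, adjusted p = 0.00223, Fisher's exact test), with 79.0% ± 0.35 at Grb10 and 58.0% ± 12.69 at Dlk1 (SD, n = 2). Among genes of Polycomb proteins and cell cycle inhibitors 18 of 37 were marked (48.6%, adjusted exact p = 0.0247), led by Cbx8, itself a Polycomb component, at 90.8% ± 1.85, and Cdkn2a, the locus of cell cycle inhibitors p16 and Arf, at 80.7% ± 2.58. Ezh2, Eed and Suz12, the core of the complex that writes the mark, were unmarked. This list had 33 high-CpG promoters, and against genes of the same CpG class it did not pass (adjusted permutation p = 0.179). Neither did it when at least 25% of the promoter window had to be covered (adjusted exact p = 0.133). Of 42 germ cell genes 11 were marked (26.2%, adjusted exact p = 0.772), with 43.1% ± 5.81 at Prdm14 and 36.6% ± 0.14 at the pluripotency gene Pou5f1.

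Domains over the 4 Hox clusters were among the 6 longest. Merging the replicated peaks gave 20078 domains with a median length of 1993 bp, 632 of them at least 20 kb long and 70 at least 50 kb. Of the 632, 488 (77.2%) held a protein-coding 5′ end. The longest, at 257.3 kb on chromosome 15 from 102893219 to 103150556, held 9 Hoxc genes, Hoxc13 to Hoxc4, in 64 separate peaks, and peaks of the replicates covered 87.8% ± 1.43 of it (SD, n = 2). HoxA with Evx1 lay in a domain of 184.3 kb on chromosome 6 from 52144965 to 52329267, with 86.3% ± 0.07 covered. Hoxb9 to Hoxb1 lay in one of 153.5 kb on chromosome 11 from 96232314 to 96385812, with 87.2% ± 0.01, and Hoxb13 in a separate domain of 80.0 kb. HoxD with Evx2 took 127.4 kb on chromosome 2 from 74643376 to 74770816, with 94.4% ± 1.19. The second longest, 195.1 kb on chromosome 13 from 45173050 to 45368110, held no protein-coding 5′ end. It contained the 5′ ends of the annotated genes Gm8513, Gm47448, Gm34466 and Gm23755, none of them protein-coding, and 60.5% ± 1.63 of it was covered. The nearest protein-coding 5′ end was that of Mylip. The other long domains held Rhcg and the microRNA gene Mir9-3 (133.9 kb, chromosome 7), Mcf2l (107.7 kb, chromosome 8), Tbx2 with Gm11444 (105.6 kb, chromosome 11), 6430628N08Rik with Dmbx1 (101.5 kb, chromosome 4) and Pipox with Sez6 (93.8 kb, chromosome 11). The 5 replicated peaks with the highest of the authors' enrichment values lay over the 5′ ends of Onecut3 (28.1), Tmem59l together with Crlf1 (26.4), Pou3f1 (26.1), Shisa8 (25.8) and Wnt3a (25.6). Domain numbers depended on the list: a single replicate's own list gave 34788 or 35191 domains. The number of domains of 20 kb or more also moved widely over the alternatives, as given below.

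Coverage of the X chromosome was lower than that of each autosome in both replicates. Peaks covered 1.38% ± 0.215 of the X and from 1.51% to 5.03% of the autosomes (SD, n = 2). Chromosome 3, the lowest autosome, lay at 1.41% against 1.23% for the X in replicate 1 and at 1.61% against 1.53% in replicate 2. In the pooled list the X, at 2.21%, lay above chromosomes 3 and 14, at 2.00% and 2.12%. The ratio of X to autosomal coverage was 0.544 ± 0.0337 (SD, n = 2). Of 948 X-linked protein-coding genes 203 were marked (21.4%), against 6175 of 20807 autosomal genes (29.7%), with a two-sided Fisher's exact p of 2e-08. That test was not fixed in advance, and it treats neighbouring genes as independent, so its p may overstate the difference. On single autosomes the share of marked genes ranged from 23.4% to 39.2%, a spread between chromosomes that the test does not measure. The pooled list put 57.7 peaks per Mb on the X, close to the autosomal median of 55.7, but the replicated list kept 32.1% of them, against 36.9% to 43.9% on each autosome. Restricting each replicate to peaks with a −log10 q of at least 5 lowered the coverage ratio to 0.268.

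**Figure D4:**
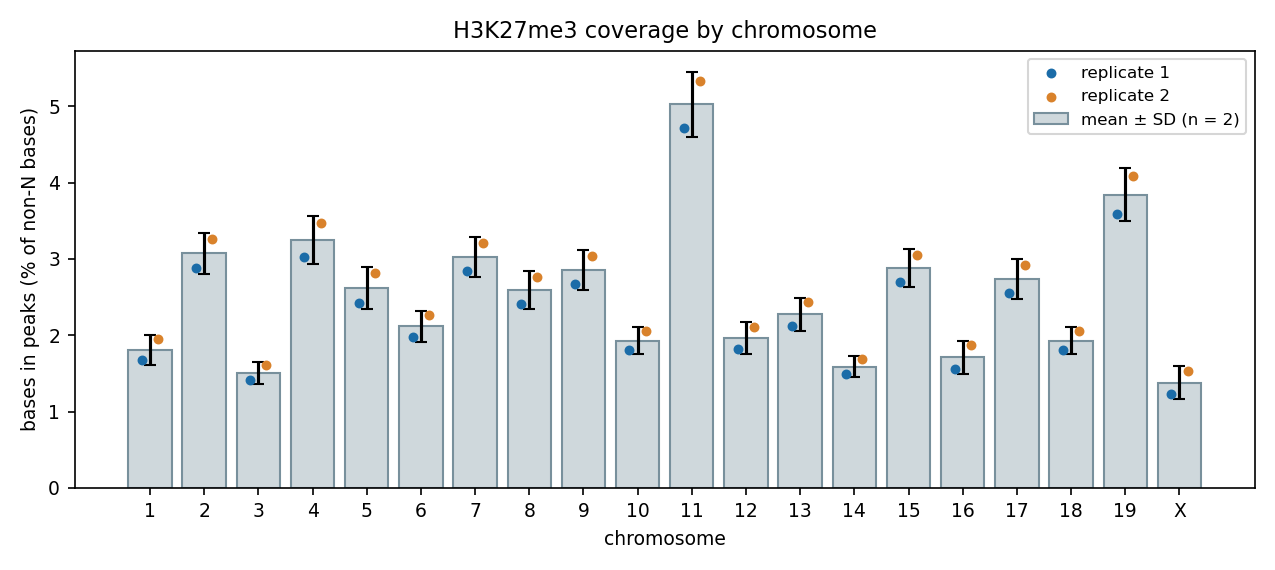
Bases in peaks (y axis, % of non-N bases) on each chromosome (x axis); bars are the mean of the replicates' own lists, error bars the SD (n = 2) and points the replicates. Chromosome 11 was highest at 5.03% and the X lowest at 1.38%.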

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

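Gene list tests that rotated the marked genes along the gene order or left out X-linked genes, and the 50% rule for replicated peaks not matched in both replicates' lists, were chosen after the data were seen. No paired analysis was possible because there was a single group. Of 286 combinations of 22 lists and 13 alternatives, 269 kept their direction and their side of the threshold, and 12 lists did so throughout. The number of marked genes ranged from 5618 with at least 25% of the window covered to 7613 with the pooled list. The overlap of replicate 1 peaks stayed above shifted lists in each alternative, from 46.9% with at least 50% of the peak covered to 85.5% for the top 10% of the peaks by −log10 p. For replicate 2 peaks at least 50% covered it was 35.3%. The odds ratio of high-CpG to low-CpG promoters ranged from 3.12 to 5.70. Leaving out a replicate gave 3.12 and 3.43.

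Adult hepatocyte metabolism genes were the least settled list, with a main ratio of 0.501 to other genes and adjusted p from 0.0187 to 0.931 over the alternatives. The ratio was 0.473 to 0.698 with 1 replicate left out, and the call was lost on the replicate 2 list (adjusted exact p = 0.204). It was also lost with the pooled list (0.6), with a −log10 q of at least 5 (0.55), with at least 25% of the window covered (0.569), with a background of the same CpG class (0.895) and under rotation along the gene order (0.501, adjusted permutation p = 0.0536). The Polycomb and cell cycle inhibitor list fell from a ratio of 1.68 to 1.48 with at least 25% of the window covered and to 1.36 with the CpG background, and both ended the call. Circular shifts ask whether peaks meet a list more often than random positions do, a different question by construction. Their ratios were 6.48 for hepatocyte, 3.98 for erythroid, 5.86 for myeloid, 5.56 for lymphoid, 6.23 for gut and 5.45 for germ cell genes, which all passed only there. Housekeeping genes lost their call (0.537), and adult hepatocyte metabolism genes (2.63) and Zfp genes (2.97) turned from below to above 1. Except for the CpG background and the shifts, the cause of these changes was not tested.

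The replicated list had 34214 peaks with a −log10 q of at least 5, and 33380 pooled peaks were covered over at least 50% in both replicates. By the latter rule 23431 replicated peaks, not 11284, lacked a match in at least 1 replicate's list. Domains numbered 34788 to 35191 when 1 replicate's own list was used. Domains of 20 kb or more numbered 317 to 1664 over the alternatives. The ratio of X to autosomal coverage was 0.652 in the pooled list, 0.479 in the replicated list, and 0.498 and 0.268 with a −log10 q of at least 2 and 5. For the share of promoters marked, instead of coverage, the ratio of X to autosomes was 0.789. That value is the mean of the ratios from each replicate's own list, not from the replicated list. The causes were not tested here. Unknown read depth limits what a missing narrow peak means, since a peak absent from a list can be a peak below the detection limit. For the 89 named genes, 126 of 445 alternative values of the 20 kb coverage moved by more than the SD of the replicates, which with n = 2 was often under 1 percentage point.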

Other observations

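The tests of gene families, of weak peaks missed by a single replicate, of X copy number, of X peaks in 10 bins and of hepatocyte promoters were chosen after the results they bear on had been seen. Protein-coding genes were also grouped by the letters before the first digit of their symbol. The stems Gm, Olfr and Zfp and symbols ending in Rik were left out, the Olfr and Zfp genes being tested as gene lists above. The remaining 267 families with at least 10 members were tested with two-sided Fisher's exact tests, adjusted over these families. More often marked than other genes were 48 families, and 40 were marked less often. Semaphorin genes, which guide axons, were marked in 19 of 20 cases (adjusted exact p = 8.1e-08), synaptotagmin genes of vesicle release in 16 of 17 (1.21e-06), Nkx homeobox genes in 14 of 14 (1.21e-06) and protocadherin genes with the plain Pcdh stem in 12 of 12 (9.66e-06). Collagen genes were marked in 31 of 45 cases (1.24e-06), Frizzled receptor genes in 9 of 10 (0.00122) and serotonin receptor genes with the Htr stem in 12 of 14 (0.000248). With the replicates' own lists 46 families were higher in each case, and 43 and 44 of the 48 were among them.

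At the low end, 0 of 331 vomeronasal receptor genes (Vmn) were marked in the replicated list, and 0 in either replicate's own list. Histone genes with the Hist stem were marked in 1 of 67 cases (adjusted exact p = 3.6e-07) although 64 had high-CpG promoters, and Mrpl genes of the mitochondrial ribosome in 3 of 49 (0.00122). Of the 40 low families 14 lay on a single chromosome each, where neighbours share peaks, and so did 3 of the 48 high ones, Hoxa, Hoxb and Pcdhga. In the clustered protocadherins on chromosome 18, 9 of 12 Pcdhga genes, 0 of 22 Pcdhb genes and 0 of 12 Pcdha genes were marked, a contrast picked after the values were seen, among neighbours that share peaks. The marked olfactory receptor genes Olfr64 and Olfr65 have their 5′ ends at positions 103894485 and 103903487 of chromosome 7, near the unmarked Hbb-bt at 103813996.

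The 11284 replicated peaks without a peak in both replicates' own lists are a pattern of the processing. If they were kept by the strength of the pooled peak alone, the −log10 q would separate kept from dropped peaks. Among the 68159 pooled peaks found in exactly 1 replicate, the area under the curve of −log10 q was 0.776. That argues against a cut on −log10 q alone for these peaks. Other measures of strength, and the 317 replicated peaks that both replicates lacked, were not covered. Weak peaks missed by a single replicate stay open: 90.4% of the peaks in question had a −log10 q below the median of the other replicated peaks, but peaks picked for a missing call are weak nearly by construction. Rules that split the pooled reads were not tested. No biological explanation was tested.

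The second pattern is that X peaks were replicated less often, 32.1% against 40.5% of autosomal pooled peaks. Weaker X peaks may account for most of the lower share: autosomal peaks of the same −log10 q, in 20 bins, were replicated in 32.4% of cases, so the X differed by -0.283 percentage points, within the range of single autosomes from -0.992 to 1.549. With 10 bins it differed by -1.034, just outside the autosomal range of -0.994 to 1.488. Fewer X copies in a pool of both sexes stay open as a reason for weaker peaks, since the median −log10 q was 3.01 on the X and at least 3.22 on each autosome, although the pooled list had 57.7 peaks per Mb on the X against an autosomal median of 55.7. Scattered signal between genes, as a diffusely marked inactive X could give, stays open too, since narrow peaks far from promoters numbered 39.3 per Mb on the X, above 18 of 19 autosomes but below the highest at 48.5, and with the sexes pooled a difference between them was not testable.

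The third pattern is the marked promoters among hepatocyte genes, 16 of 48, in a tissue that holds hepatoblasts. A high CpG content did not bring the mark whatever the gene, since only 3866 of all 10422 high-CpG promoters (37.1%) were marked. Among high-CpG promoters, 9 of 10 of hepatocyte genes and 0 of 32 of housekeeping genes were marked (two-sided Fisher's exact p = 2.24e-08). That contrast was picked after the values were seen, so its p adds no support and does not tell why the hepatocyte promoters were marked. It also leaves aside the marked low-CpG promoters such as Hnf1a, Nr5a2 and Nr1i3. That the CpG class sets the share stays open: 10.1 marked genes were expected at the shares of their classes, and the excess did not pass (adjusted permutation p = 0.0766). Signal from blood cells of the tissue, in which these genes are silent, may contribute and predicts that erythroid promoters are spared, but with 6 of 12 high-CpG erythroid promoters marked the difference did not pass (two-sided Fisher's exact p = 0.0743). In the other blood lists, high-CpG promoters were marked in 10 of 10 myeloid and 5 of 7 lymphoid cases. Peak lists of whole liver do not assign a marked promoter to a cell type. Such counts therefore cannot tell blood cells and hepatoblasts apart as sources, whatever the number of promoters.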
